A study of Xenopus laevis with 20 samples.

How the data were processed

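RNA from animal caps of Xenopus laevis, the cap of ectoderm cut from the blastula, was measured on 20 single-colour oligonucleotide arrays in 5 groups of 4: uninjected, Gata4-GR, Gata5-GR, Dkk1, and Gata4-GR with Dkk1. Per the labels' protocols, 10 ng of each mRNA was injected before the first cleavage, caps were cut at stage 9 and were kept for 2.5 hours in cycloheximide, which blocks protein synthesis, and dexamethasone, which activates the glucocorticoid receptor (GR) fusions. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate batches of embryos, so p-values measure the spread between these arrays, which may be partly technical.

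The deposited values are probe-set intensity values on a linear scale, 1 per row and array, as the values themselves show. Per the labels, labelling followed the standard protocol of the array's maker; the software that summarised the probes is not given in the sources used here. The 15611 rows held signals from 0.1 to 10929. The trimmed mean of an array, with 2% left off at each end, ran from 143 to 240, so the arrays had not been scaled to a common level. Each signal had 16 added and was taken to log2, and the arrays were quantile normalized. A fold change is therefore on the log2(signal + 16) scale and understates the change of dim rows. The 120 rows listed as controls were left out, and 15491 rows were tested, with no filter on dim rows.

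The row identifiers could not be used to name genes. Every gene's name would come from the identifier beside its signals, and the following checks, chosen after the values were seen, bear on that pairing; the first 3 speak against it. X. laevis keeps L and S copies of many genes from a genome duplication, and over 1017 listed L and S pairs the median log2 signals had a correlation across genes of -0.013 (permutation p = 0.677, 10000 permutations; genes are not independent replicates). Over 1109 pairs of rows listed under 1 symbol in different sequence clusters the correlation was 0.0077 (permutation p = 0.793). Their profiles over the 20 arrays, in which a probe's own brightness drops out, correlated at a mean of 0.00091 with a standard error of 0.0083 (permutation p = 0.489). The 251 pairs of probe sets of 1 cluster that differ in an x ending correlated in signal at 0.299, but neighbouring rows of any kind did so at 0.374. The profiles of these pairs correlated at a mean of 0.046 with a standard error of 0.021 (permutation p = 0.00699 against shuffled pairs, 1000 permutations), and those of neighbours in different clusters at 0.033. The 3 rows listed for the bacterial control RNA bioB in its first probe design had a median signal of 126, and the 3 rows listed for bioB in its second design 7496, although different probes need not read alike for 1 RNA. Rows 25 to 33 repeated the profile of rows 1 to 9 with a correlation of 0.989, the highest of 103 windows searched among the control rows. In uninjected replicate 3, rows 1 to 9 differed from the median of the other arrays by a mean log2 of -3.08, and rows 25 to 33 by 0.26, so the control rows do not settle which order is right. No array with trusted identifiers was used to show what correlations to expect. A search over 1140 sort orders of the identifiers was made after these checks were seen. Its highest L and S correlation was 0.108, the maximum of that search, and its highest median percentile of ribosomal protein rows was 68.5, against 42.6 in the listed order. No order was adopted from it. The annotation table pairs 9304 probe sets with 1 symbol and 195 with several, and none of these names is used. Rows are given by their position in the deposited table, counted from 1. The 15 gene lists and the rule for named genes that had been fixed before the data were examined need gene names, so they were not tested, and the rows described were chosen after their values were seen: they are all the rows called in any comparison. The comparisons of groups need only the columns, which carry the sample labels. Leaving out the 120 control rows does rest on the listed identifiers, and the counts of calls were the same with all 15611 rows tested.

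limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 20 arrays, with eBayes moderated two-sided tests and Benjamini-Hochberg adjustment over the rows of each of 7 comparisons. A row was called at an adjusted p under 0.05. These tests, the pseudocount and the alternatives were fixed before the data were examined, apart from 4 alternatives added later: no normalization between arrays, scaling to a common trimmed mean, all rows tested, and the replicate block without Gata4-GR replicate 1. The fit was tested on simulated arrays with the spread of the real rows and a replicate effect common to all groups. For Gata4-GR against uninjected, with 15491 rows simulated, it recovered 81% of 100 rows changed 2-fold and 98% of 100 changed 4-fold on the log2(signal + 16) scale, with 0 false calls. With the replicate number as a block these shares were 96% and 100%, with 8 false calls. That share of false calls is within what an adjusted p under 0.05 allows. Both sets of 100 rows were changed at once, which eases the adjustment over the rows. On the real arrays the fit without a block called at most 5 rows in a comparison, so these shares overstate its recovery there. Row 2912, for example, rose by a log2 of 1.18 in Gata5-GR caps over uninjected caps and was not called (limma adjusted p = 0.283). The number of arrays limits the precision.

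Replicate numbers in the titles were checked for pairing by the correlation of deviations from the group means, with r over 0.1 in every pair as the bound. Same-numbered arrays of different groups correlated at a median of 0.517 over 40 pairs, with a range of 0.060 to 0.659, and differently numbered arrays at a median of -0.168. Deviations cancel within a group, so positive values for same numbers bring negative ones for the others, which are no separate evidence. Every pair passed except Gata4-GR replicate 1 with uninjected replicate 1, at 0.060. By this bound the numbers pair the samples in 5 of the comparisons, and not in Gata4-GR against uninjected or in the interaction. For Gata4-GR with uninjected arrays, numbers 2, 3 and 4 had r of 0.384, 0.440 and 0.569. The missed bound therefore does not show that these samples were unpaired. Calls with the block had been seen together with this check, and the bound was kept as fixed beforehand.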

Results

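Transcript signals were measured in 20 samples of Xenopus laevis animal caps, 4 in each of 5 groups. Gata4 and Gata5 are zinc-finger transcription factors of endoderm and heart mesoderm, and Dkk1 is a secreted inhibitor of canonical Wnt signalling. The Gata proteins were supplied as fusions to the glucocorticoid receptor (Gata4-GR and Gata5-GR), which dexamethasone makes active, and cycloheximide was present so that changes would not need new protein. All groups had both drugs, and the uninjected caps were the common control. No group was injected with a control RNA, so a comparison with uninjected caps also holds any effect of the injection itself. Dkk1 was not a GR fusion and was injected before the first cleavage, so its changes could begin before the drugs were added. The median signal of an array lay between 59.2 and 101. Rows are given by position because the identifiers listed beside the signals could not be relied on. The L and S copies of 1017 genes had a correlation of -0.013 across genes in signal. Rows listed under 1 symbol had profiles over the arrays that correlated at a mean of 0.00091. No row below is tied to a gene.

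The first comparison asked which transcripts respond at once to Gata4. With 1 mean fitted per group, 2 of 15491 rows were called higher in Gata4-GR caps than in uninjected caps and 0 were called lower. Row 5066 read between 1.3 and 2.7 in the uninjected arrays and between 1710 and 6272 in the Gata4-GR arrays. Its normalized log2 level was 4.16 ± 0.05 (SD, n = 4) in uninjected caps and 11.28 ± 0.86 (SD, n = 4) in Gata4-GR caps. The log2 fold change was 7.12 with a standard error of 0.47 (limma adjusted p = 6.65e-08), and it was higher in 4 of 4 same-numbered pairs. The uninjected signals lay far below the added 16, so the size of this change depends on it: the log2 fold change was 9.76 with a pseudocount of 1 and 5.27 with 64. Whether row 5066 detects the injected Gata-GR RNA itself or a transcript that responds to Gata4 cannot be told apart here. Row 11897 rose from 5.07 ± 0.13 to 6.36 ± 0.31 (SD, n = 4), a log2 fold change of 1.29 with a standard error of 0.16 (limma adjusted p = 0.00113), again in 4 of 4 pairs. At an unadjusted p under 0.05 there were 716 rows, against 774.55 expected by chance. With only rows brighter than the median row tested, the count was 1, row 5066; row 11897 is dimmer than that. The count was also 1, row 5066, with only the arrays of both groups fitted. With the replicate number as a block, for which this comparison missed the pairing bound, 4 rows were called. Added were row 15271 (adjusted p = 0.0247) and row 2140 (adjusted p = 0.0387), both lower. Rows at an unadjusted p under 0.05 then numbered 1601. Without Gata4-GR replicate 1 the blocked fit called 3 rows.

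The second comparison put the same question for Gata5. Gata5-GR caps had 5 rows higher than uninjected caps and 0 lower. Row 5066 was again the largest change, with a log2 fold change of 7.30 and a standard error of 0.47 (limma adjusted p = 4.22e-08). Row 11897 rose by 1.16 with a standard error of 0.16 (limma adjusted p = 0.00534). Row 821 rose by 1.23 (limma adjusted p = 0.00545), from signals of 0.7 to 6.5 in uninjected arrays to 18.9 to 37.1 in Gata5-GR arrays. Row 15572 rose by 1.55 and row 3106 by 1.19, each with a limma adjusted p of 0.0211. Row 15572 read 5.5 to 17.1 in uninjected arrays and at least 18 in the arrays of every injected group. Its highest group mean was with Dkk1 by itself, so its rise is not particular to Gata5-GR and may hold an effect of the injection. All 5 rows were higher in 4 of 4 pairs. The calls of rows 15572 and 3106 were the least secure: the count was 3 without uninjected replicate 3, uninjected replicate 4, Gata5-GR replicate 2 or Gata5-GR replicate 4, or with only the arrays of both groups fitted. With the replicate number as a block, row 2912 was also called higher (adjusted p = 0.00843) and row 15271 lower (adjusted p = 0.0119), for 7 rows in all.

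Both rows called with Gata4-GR were among the 5 called with Gata5-GR. Simulated unchanged groups sharing the uninjected arrays gave at most 0 such rows in 20 simulations, which says little because the fit made 0 calls where nothing changed. Independent lists of these sizes would share 0.000646 rows. Row 5066 is 1 of the shared rows, and if it detects the injected Gata-GR RNAs it would be shared without a common response. With the uninjected arrays divided so that each comparison had its own 2, the overlap was 1 row in each of 6 divisions. Over all rows the fold changes of both comparisons had a correlation across rows of 0.563, against 0.501 in simulated unchanged groups, and a covariance of 0.0195 against 0.0119. Without the 6 called rows the correlation was 0.517 and the covariance 0.0160. With the controls divided, the covariance ran from -0.0087 to 0.0030. The divided controls had different replicate numbers, whose effects then do not cancel, and simulated unchanged groups gave -0.0134 to -0.0113. The observed covariance exceeded the simulated one by 0.0027 to 0.0164 over the 6 divisions, and by 0.0077 with the controls undivided. These excesses include the called rows. With the controls divided they were not computed without those rows, so they do not show a change shared across the other rows. Compared directly, Gata5-GR and Gata4-GR caps had 0 rows called different by limma, with or without the replicate number as a block. At an unadjusted p under 0.05 there were 538 rows without the block and 1309 with it, against 774.55 expected by chance; without Gata4-GR replicate 1 the blocked number was 820. For row 5066 the log2 difference of Gata5-GR and Gata4-GR was 0.18 with a standard error of 0.47 (limma adjusted p = 0.999). Among the 6 called rows the largest such difference was 1.12 in row 15572, with a standard error of 0.25. It was higher in 4 of 4 pairs and was not called (limma adjusted p = 0.999, and 0.109 with the block), so the lack of calls does not show equal levels.

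The third comparison asked which transcripts respond to Gata4 when Wnt signalling is inhibited. Gata4-GR+Dkk1 caps had 2 rows higher than Dkk1 caps and 0 lower, and both were the rows called for Gata4-GR without Dkk1. Independent lists of these sizes would share 0.000258 rows. Row 5066 would also be shared if it detects the injected Gata4-GR RNA, which both comparisons hold. Row 5066 rose by 3.88 with a standard error of 0.47 (limma adjusted p = 0.00156), from 6.69 ± 1.04 in Dkk1 caps to 10.57 ± 0.36 (SD, n = 4). Row 11897 rose by 1.06 with a standard error of 0.16 (limma adjusted p = 0.0177), and both rows were higher in 4 of 4 pairs. The count was 1, row 5066, without Dkk1 replicate 1, 2 or 4, or without Gata4-GR+Dkk1 replicate 1, 3 or 4. It was 0 with only the arrays of both groups fitted. With the replicate number as a block 4 rows were called, adding row 2207 and row 8294, each with an adjusted p of 0.0372.

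With Dkk1 by itself, 2 rows were called higher than in uninjected caps and 0 lower. Row 2234 had signals of 458.5 to 645.4 in the Dkk1 arrays and 18.8 to 135.2 in the uninjected arrays, a log2 fold change of 3.55 with a standard error of 0.49 (limma adjusted p = 0.00573). Row 15572 rose from 4.78 ± 0.28 to 7.23 ± 0.35 (SD, n = 4), a log2 fold change of 2.45 with a standard error of 0.25 (limma adjusted p = 0.000128). Each was higher in 4 of 4 pairs. Row 15572 also lay above all uninjected arrays in every other injected group, so part of its rise may be an effect of the injection. Row 2234 was high in both groups given Dkk1 RNA. Whether it detects that injected RNA itself or a transcript that responds to Dkk1 was not tested. Row 5066 had a log2 difference of 2.53 that was not called (limma adjusted p = 0.174), although all 4 Dkk1 arrays lay above all uninjected arrays. It was called with a pseudocount of 1 (adjusted p = 0.000407; 0.000407 to 1 over its alternatives) and with the replicate number as a block (adjusted p = 0.00156), where 3 rows were called.

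With Dkk1 added to Gata4-GR, 1 row was called higher than with Gata4-GR and 0 lower. It was row 2234, with a log2 fold change of 3.73 and a standard error of 0.49 (limma adjusted p = 0.00562), and it was higher in 4 of 4 pairs. The call was lost with a pseudocount of 1 (adjusted p = 0.0519; 6.2e-06 to 0.085 over its alternatives), and with the replicate block without Gata4-GR replicate 1 the count was 0. Its signals were 466.2 to 612.3 in Gata4-GR+Dkk1 arrays. In Gata5-GR arrays, which had no Dkk1, this row ranged from 22.7 to 373.6. Gata4-GR+Dkk1 and Dkk1 caps differed in it by a log2 of -0.18 with a standard error of 0.49. Here too, detection of the injected Dkk1 RNA was not tested, because the row has no reliable identifier. The interaction asks whether the Gata4-GR effect differed with and without Dkk1. It gave 0 rows by limma, with 353 at an unadjusted p under 0.05 against 774.55 expected by chance. With the replicate number as a block there were 741. The fit without a block leaves the differences between replicate numbers in its spread, so a number below chance does not show a lack of response. For row 5066 the interaction was -3.23 with a standard error of 0.67 (limma adjusted p = 0.99). Its larger part was the rise of 2.53 in Dkk1 caps over uninjected caps. Between Gata4-GR+Dkk1 and Gata4-GR caps the row differed by -0.70 with a standard error of 0.47 (limma unadjusted p = 0.152). Whether the interaction of row 5066 was called depended on the setting. With a pseudocount of 1 it was -5.61 and was called (adjusted p = 0.0153). The replicate number as a block also gave a call (adjusted p = 0.0123), although this comparison missed the pairing bound. The adjusted p ran from 0.0123 to 1 over the alternatives.

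**Figure D1:**
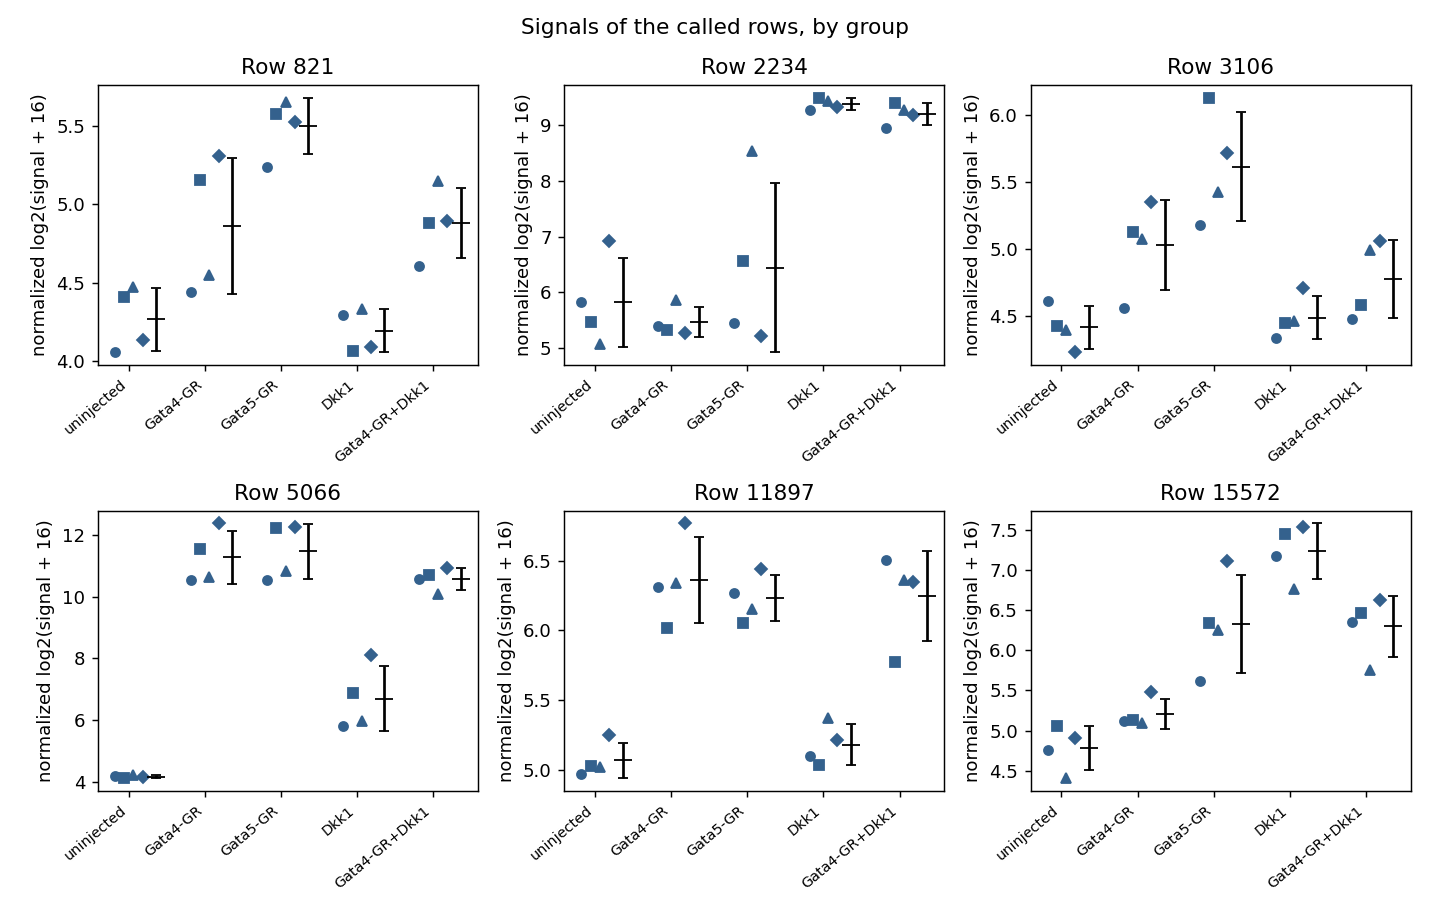
Normalized log2(signal + 16) on the vertical axis for each of the 6 called rows, by group on the horizontal axis. Each point is an array, with a marker shape for each replicate number, and the bar beside them is the mean with its SD over 4 arrays. Row 5066 has a mean of 4.16 in uninjected caps and of 11.28 in Gata4-GR caps, and row 2234 has its highest means in both groups given Dkk1.

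The arrays differed more by replicate number than by group. The first principal component held 22.8% of the variance, and 97.5% of it lay between replicate numbers against 0.88% between groups. All 20 arrays had their closest array of another group at their own number. Gata4-GR replicate 1 had the lowest mean correlation with the other arrays, at 0.959, and an array weight of 0.275. Uninjected replicate 3 had a mean signal of 244 in rows 4 to 9, where the other arrays read 1671 to 2908.

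**Figure D2:**
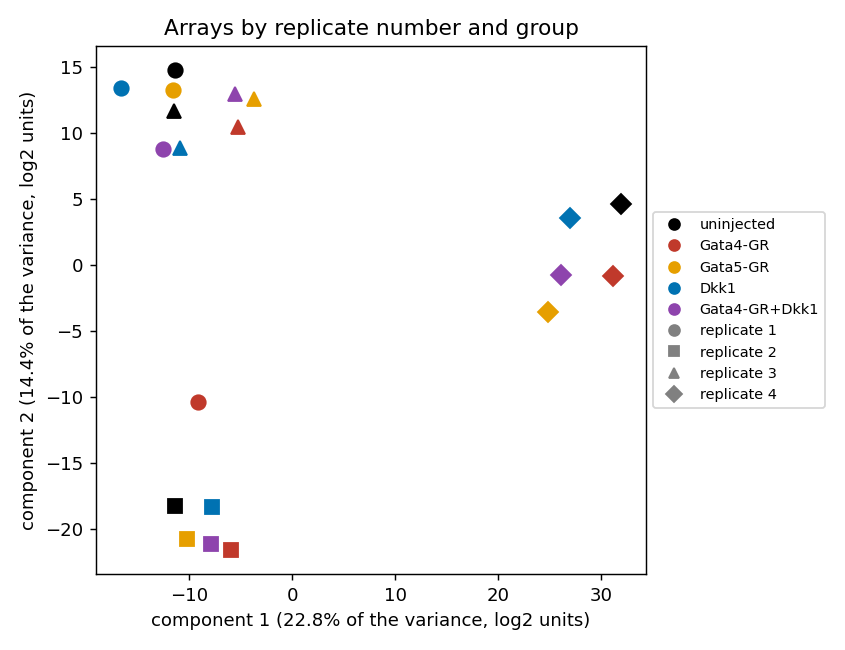
Scores of the 20 arrays on the first principal component (horizontal, 22.8% of the variance) and the second (vertical, 14.4%), in log2 units. Colour gives the group and marker shape the replicate number, and the arrays of replicate 4 lie apart from the others along the horizontal axis.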

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

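In this part the tests on row 5066 were chosen after its values were seen, and the splits of the arrays were planned. Of 45 groups of 4 values checked for an array standing apart, 1 was found, and chance gives about 2.25. In row 15572, Gata4-GR replicate 4 read 35.9 where the other Gata4-GR arrays read 18 to 22.7. The Gata4-GR effect differed with and without Dkk1 in 2 of the 6 called rows when the interaction was adjusted over those 6 rows alone, by limma. The difference was -3.23 in row 5066 (adjusted p = 0.000642) and -1.36 in row 15572 (adjusted p = 0.00363). In row 5066 the larger part of it was the rise of 2.53 in Dkk1 caps over uninjected caps. Gata4-GR+Dkk1 caps differed from Gata4-GR caps by -0.70 with a standard error of 0.47. The rows had been picked for changes between these groups, so this adjustment is too lenient. Adjusted over all rows, neither passed in the fit without a block at a pseudocount of 16, and row 5066 passed at a pseudocount of 1 (adjusted p = 0.0153; 0.0123 to 1 over all its alternatives).

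Row 5066 read at least 30.8 in the 16 injected arrays and at most 2.7 in the uninjected ones. A response to Gata activity alone is argued against by the Dkk1 arrays, which all lay above all uninjected arrays (exact two-sided permutation p = 0.0286, the smallest that 4 arrays against 4 give). A sequence common to all injected RNAs at an equal dose is argued against by the log2 difference of 4.59 between Gata4-GR and Dkk1 arrays. A candidate explanation that stays open is that the row detects the Gata-GR RNAs themselves, with some carry-over into the Dkk1 caps, whose median signal was 2.92% of the Gata4-GR median. It cannot be told apart from a transcript induced by Gata with the same carry-over, because the row has no reliable identifier.

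Other groupings of the same arrays tested whether the counts of calls could arise by chance. For Gata4-GR against uninjected, 1 of 35 splits, the real one, gave as many as 2 rows, and the highest other gave 0. The real split was likewise the only 1 of 35 for Gata5-GR (5 rows, highest other 2), Gata4-GR+Dkk1 against Dkk1 (2 rows, highest other 0), Dkk1 against uninjected (2 rows, highest other 1) and Gata4-GR+Dkk1 against Gata4-GR (1 row, highest other 0). Chance is excluded for these 5 counts only if all 35 splits are taken as equally likely. In the 4 of these comparisons where the numbers pair the samples, 8 splits, the real one included, part all 4 same-numbered pairs, and the others leave same-numbered arrays together. The 7 other splits of that kind called 0 rows, but 8 splits are too few for a share under 0.05. The same numbers hold for Gata4-GR against uninjected, where the missed bound does not show that the samples were unpaired. For Gata5-GR against Gata4-GR and for the interaction the real count was 0, which every split reaches (35 of 35 and 100 of 100), so the splits decide nothing there. The highest other counts were 0 and 2.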

How the results depend on the processing

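Quantile normalization had been planned as an alternative and became the main setting, so it gave no separate value. The gene list tests and their alternatives were not run, because no gene could be named. Settings left out here kept counts within 1.5 times. Median centring gave 1 row for Gata4-GR+Dkk1 against Dkk1 and an overlap of 1 between Gata4-GR calls without and with Dkk1. Pseudocount 1 gave 0 rows for Gata4-GR+Dkk1 against Gata4-GR, 1 lower row for Gata5-GR against Gata4-GR and 1 lower row for the interaction. Pseudocount 64 gave 3 rows for Gata5-GR, 1 for Gata4-GR+Dkk1 against Dkk1 and an overlap of 1 without and with Dkk1. With rows above the 25th percentile Gata5-GR had 3 rows, and with rows above the 50th the counts were 1 for Gata4-GR, Gata5-GR, Gata4-GR+Dkk1 against Dkk1, Dkk1, and both overlaps; fewer rows were tested there. With only the compared groups fitted, the counts were 1 for Gata4-GR, 3 for Gata5-GR and 0 for Gata4-GR+Dkk1 against Dkk1, from fewer arrays. At an adjusted p under 0.01 they were 3 for Gata5-GR, 1 for Gata4-GR+Dkk1 against Dkk1 and 1 for its overlap. Otherwise the cause was not tested.

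With the replicate block, the count was 4 for Gata4-GR against uninjected (2 higher, 2 lower), 4 for Gata4-GR+Dkk1 against Dkk1 and 1 for the interaction, which was row 5066 (adjusted p = 0.0123; over all its alternatives 0.0123 to 1). Every array lay closest to its own number, a hint of pairing in Gata4-GR against uninjected too, where the pairing bound was missed. For Gata4-GR replicate 1 the hint is weak, since its closest correlation was 0.136. The block ended none of the main calls. For Gata4-GR against uninjected, rows at an unadjusted p under 0.05 rose from 716 to 1601 with the block, and numbered 1016 with the block and without Gata4-GR replicate 1, where chance gives 774.55.

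Leaving out each array in turn gave 2 to 2 rows for Gata4-GR, 3 to 6 for Gata5-GR, 1 to 2 for Gata4-GR+Dkk1 against Dkk1, and overlaps of 2 to 3 between Gata4-GR and Gata5-GR and of 1 to 2 without and with Dkk1. Of alternatives chosen after seeing the data, no normalization gave 2 rows for Gata5-GR, 1 for Gata4-GR+Dkk1 against Dkk1 and overlaps of 1 and 1, and scaling to a common trimmed mean gave 1 for Gata4-GR+Dkk1 against Dkk1 and an overlap of 1. The replicate block without Gata4-GR replicate 1 gave 8 for Gata5-GR, 5 for Gata4-GR+Dkk1 against Dkk1, 4 for Dkk1, 0 for Gata4-GR+Dkk1 against Gata4-GR and 1 for the interaction. None of the fold changes of the rows given by position reversed in the comparisons where the main fit or the block called them. Row 5066 kept its call for Gata4-GR in 22 of 22 settings, with adjusted p from 3.84e-10 to 3.43e-05. Row 11897 lost its call in Gata4-GR+Dkk1 against Dkk1 in 11 of 21, row 15572 lost its Gata5-GR call in 9 of 21, and row 3106 lost its call in 8 of 20; a filter that left a row out gave no value for it. Rows 821 and 3106, and rows 5066, 11897 and 15572 in uninjected caps, had signals far below the array medians, where the added 16 sets much of the fold. With pseudocounts of 64 and 1 the log2 fold change of row 15572 for Dkk1 was 1.40 and 3.50. That of row 11897 for Gata4-GR against uninjected was 0.68 and 1.85.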

Other observations

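In this part the tests of the identifiers and of the shared source were chosen after the values were seen, and the test of array brightness was written before its result. A hypothesis is that the identifiers and the signals of the deposited table stand in different orders. Such orders are consistent with the correlation of -0.013 between L and S copies. Little ribosomal protein RNA in the caps, with correct identifiers, is argued against by the profiles of rows listed under 1 symbol, which correlated over the arrays at a mean of 0.00091 with a standard error of 0.0083. A plain sort of the identifiers is argued against by a highest correlation of 0.108 over 1140 orders. Where such a mismatch would have arisen was not tested, and no biological explanation was tested.

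Same-numbered arrays deviated together in all groups, but only weakly for Gata4-GR replicate 1. Its correlations with the arrays of number 1 in the other groups ran from 0.060 to 0.136. A source shared by arrays of 1 number, such as a batch of embryos or a day of processing, is consistent with a permutation p of 0.0001, the smallest that 10000 permutations give. Array brightness as the whole cause is argued against by a median correlation of 0.461 after the trimmed mean was fitted per row, against 0.517 before. The labels name no batch, so embryos and processing stay open.

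With the replicate block, rows at an unadjusted p under 0.05 numbered 1113 for Gata4-GR+Dkk1 against Gata4-GR, where chance gives 774.55, and 714 without Gata4-GR replicate 1. The number for Gata5-GR against Gata4-GR fell likewise. The numbers of the other paired comparisons, which do not use that array's group, rose when it was left out of the fit. They went from 693 to 918 for Gata5-GR against uninjected, from 757 to 1123 for Dkk1 against uninjected and from 571 to 762 for Gata4-GR+Dkk1 against Dkk1.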
